A study of Mus musculus with 9 samples.

How the data were processed

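RNA from the dorsal telencephalon of newborn mice was sequenced in 9 libraries, 3 each labelled wild type (WT), Tcf4 heterozygote (Het) and Tcf4 knockout (KO). Dissected tissue was snap frozen and total RNA was purified with an RNeasy Plus kit, per the labels' protocols, and libraries were made with an NEBNext Ultra RNA kit. The labels do not say whether each library came from 1 pup or from 1 litter, so p-values measure the spread between these samples.

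The authors deposited raw read counts per gene for all 9 libraries and a second table of FPKM values. The submitters' processing notes name the mouse build mm10, Bowtie2 2.0.6, TopHat2 2.0.9, HTSeq 0.6.1 and DESeq 1.10.1, without giving the role of each. The deposited FPKM values equal the counts divided by 1 gene length and by the library total, with a largest log2 difference of 1.1e-14 between libraries, so they are not an independent measurement. The tables hold 41128 genes, of which 40254 were paired with a symbol and a position in GENCODE M21, which uses the same build. Total counts ran from 22291940 to 29445788 per library. How reads that match several genes were treated, and whether strand was used, is not given in the sources used here.

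Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr over the genotypes (minimum count 10, minimum total count 15), which left 15271 genes holding 99.9% of the reads. TMM factors, a robust quasi-likelihood fit of all 9 libraries with 1 coefficient per genotype (6 residual degrees of freedom) and Benjamini-Hochberg adjustment at 0.05 gave the calls. Adjusted p-values are from edgeR's quasi-likelihood test unless another tool is named, and the standard error (SE) of a log2 fold change is its size divided by the square root of F. CPM values use TMM-scaled library sizes. A total of 34 gene lists with at least 5 tested members, covering cell types that the dissection could hold and pathways of the newborn cortex, were tested with limma's camera on log2 CPM (prior count 2, preset correlation 0.01), with adjustment over the lists of 1 comparison. Camera with an estimated correlation and fry were run beside it.

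The comparisons, gene lists, alternatives and rule for named genes were fixed before the data were examined. The rule took Tcf4 and Tcf7l2, the genes with the largest fold in each direction (8 for KO versus WT and 5 for each other comparison) among those with adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the groups, and up to 3 called members of the 10 lists with the smallest p and 2 of any other list. The report prints part of the genes taken by this rule, and which of them to print was chosen after values were seen. Symbols of unnamed gene models and sex-linked controls were passed over. Isl1, Six3, Drd2, Rpl34, Rpl34-ps1 and Rpsa, as well as values of a named gene in a comparison whose rule did not take it, were chosen after values were seen.

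The share of each gene's 31-base words that also occur in transcripts of other genes was computed from GENCODE M21, to mark genes whose reads could be split with a copy. The alternatives were other scaling factors, other filters, DESeq2 1.42.0, limma on log2(FPKM + 1), only the genotypes compared, a replicate block, removal of Y-linked genes, Xist and genes within 20 Mb of Tcf4, a fold of at least 1.5, and leaving out each library. Chosen after seeing the data were the removal of smooth trends on GC content and length (mgcv 1.9.3) and 2 restrictions by shared words. The restriction to genes sharing no word was run first. The restriction to genes with under 5% of words shared was added after the result of the first had been seen, and both are given.

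The procedure was tested on simulated counts for 15271 genes. In the simulated KO versus WT comparison it recovered 62.7% of 67 genes changed 1.5-fold, 80.6% of 67 changed 2-fold and 93.9% of 66 changed 4-fold, with 6 false calls. Simulated Het versus WT gave 7 false calls and KO versus Het 11. Far fewer genes were changed than were called in the real data, so changes that wide were not tested. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.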

Results

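The series measured gene expression in the newborn dorsal telencephalon, the region that forms the cerebral cortex and hippocampus, of mice labelled wild type, heterozygous or null for Tcf4, which encodes a class I basic helix-loop-helix (bHLH) transcription factor. Each genotype had 3 libraries. Total counts ran from 22291940 to 23813314 in the WT-labelled libraries, from 24008445 to 29398411 in the Het-labelled libraries and from 26355671 to 29445788 in the KO-labelled libraries. The question the design poses is which genes depend on Tcf4 in this tissue and at what gene dose.

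Tcf4 (chromosome 18, 69343356 to 69689079, plus strand, build mm10) was counted at 712, 728 and 584 CPM in the WT-labelled libraries, 822, 652 and 719 CPM in the Het-labelled libraries and 638, 633 and 611 CPM in the KO-labelled libraries. The log2 fold change was -0.10 (SE 0.09, adjusted p = 0.36, n = 3 per group) for KO versus WT, 0.12 (SE 0.09, adjusted p = 0.33) for Het versus WT and -0.22 (SE 0.09, adjusted p = 0.13) for KO versus Het. Gene-level Tcf4 counts therefore did not fall with the labelled genotype. Counts summed over a whole gene cannot show the loss of a part of it, and the part that was deleted is not given in the sources used here. Genotypes below are those of the labels, and each direction between genotypes rests on them. Without WT replicate 3 the KO versus WT value was -0.20 with adjusted p = 0.046, and without WT replicate 3 or Het replicate 2 the KO versus Het value passed the threshold at adjusted p = 0.043 and 0.041. Tcf7l2, a different gene that shares the alias TCF4, had log2 fold changes of -1.16 (SE 0.42, adjusted p = 0.048) for KO versus WT and -1.25 (SE 0.42, adjusted p = 0.042) for Het versus WT. The Tcf7l2 call was lost without any 1 of the Het or KO libraries, with adjusted p from 0.070 to 0.134 for KO versus WT and from 0.064 to 0.134 for Het versus WT. WT replicate 1, at 12.9 CPM against 4.01 and 5.34 CPM in the other WT-labelled libraries, carried much of the size of the Tcf7l2 change, which was -0.50 for KO versus WT (adjusted p = 0.044) and -0.59 for Het versus WT (adjusted p = 0.024) without it.

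The first principal component of log2 CPM held 64.1% of the variance and set the WT-labelled libraries (-64.5 to -54.3) apart from the Het-labelled (20.3 to 24.9) and KO-labelled ones (35.5 to 39.0). The second held 10.7% and set Het apart from KO. Processed pseudogenes took 0.253% to 0.313% of the counts in the WT-labelled libraries and 0.0804% to 0.10% in the other 6. Mitochondrial transcripts took 1.01% to 1.14% and 0.716% to 0.840%. The early-response gene Fos had 1926 counts in WT replicate 2, against 84 and 95 in the other WT-labelled libraries. KO replicate 3 had 2730 counts of Xist and 2 of Ddx3y, whereas the other 8 libraries had at most 3 counts of Xist and at least 794 of Ddx3y, so the libraries did not hold 1 sex.

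Many genes named here overlap a gene on the opposite strand, and if strand was not used their counts can hold reads of that gene. They are Adgrg6, Bcas1, Ccna2, Cnp, Cx3cr1, Dlx6, Dusp5, Emx2os, Eps8l1, Fst, Gabra5, Grin1, Grm5, Kcnh1, Kcnq5, Kif11, Limch1, Neurod1, Nrxn3, Olig1, P2ry12, Pax6, Pcdh9, Ppp1r1b, Rarb, Reln, Rps2-ps10, Shank3, Six3, Slc1a2, Slc2a1, Sp9, Syt4, Top2a, Trp73, Txnip and Wnt7b.

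**Figure D1:**
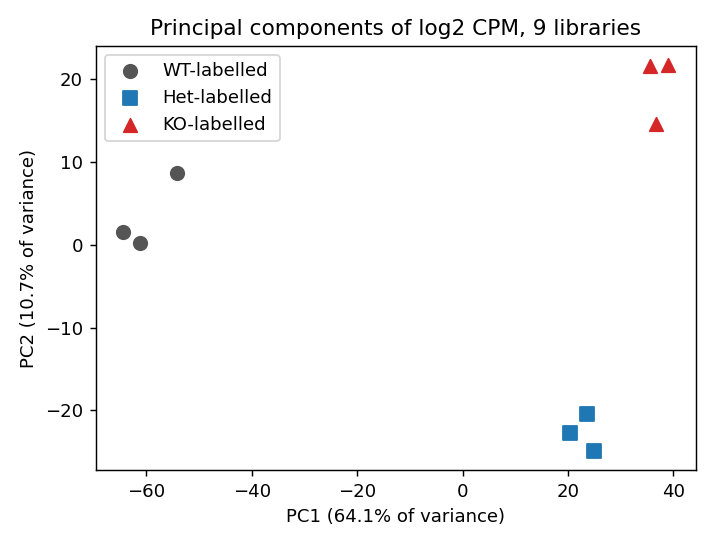
First and second principal components of log2 CPM over 15271 genes, with 1 point per library, coloured by labelled genotype. The WT-labelled libraries lie at -64.5 to -54.3 on the first component and the other 6 between 20.3 and 39.0.

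Compared with WT-labelled tissue, KO-labelled tissue had higher expression of proliferation and intermediate progenitor genes and lower expression of synaptic, glial and striatal genes. These groups passed camera with its preset correlation, and 0 of the 13 lists called in this comparison passed with an estimated correlation. Neurog2, a proneural bHLH factor of cortical progenitors, was 11.1-fold higher (log2 fold change 3.47, SE 0.11, adjusted p = 3.5e-13), at 61.8 ± 1.9 CPM in KO and 5.59 ± 0.91 CPM in WT (SD, n = 3). Slc17a7, the vesicular glutamate transporter of cortical excitatory neurons, was 3.40-fold lower, at 62.5 ± 5.1 against 213 ± 4.9 CPM. In all, 8061 of 15271 genes were called, 4042 higher and 4019 lower in KO, and 3420 of them changed at least 1.5-fold. The balance of directions depended on the setting. Limma on log2(FPKM + 1) placed 57.1% of its calls on the higher side, upper-quartile scaling factors 53.8% and the filter of 1 CPM in 3 libraries 48.4%.

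Of 32 tested cell cycle genes, 29 were higher in KO and none lower, with the same counts when adjusted over the list alone (median log2 fold change 0.87, camera adjusted p = 3.3e-11, adjusted p = 0.063 with an estimated correlation). Examples are the topoisomerase gene Top2a (log2 fold change 1.02, SE 0.07), the ribonucleotide reductase subunit Rrm2 (1.05, SE 0.08) and the cyclin Ccna2 (1.11, SE 0.09). Of 17 intermediate progenitor genes, 12 were higher and 1 lower (12 and 2 adjusted over the list alone), with camera adjusted p = 9.4e-05 and adjusted p = 0.18 with an estimated correlation. Among them Neurod1, a neuronal differentiation factor, had a log2 fold change of 2.17 (SE 0.09) and Mfng, a modifier of Notch receptors, one of 1.28 (SE 0.10). The intermediate progenitor call was lost among genes sharing no 31-base word (camera adjusted p = 0.13). Of 15 Cajal-Retzius cell genes, 9 were higher and none lower, also adjusted over the list alone, including Nhlh2 (1.59, SE 0.15) and Trp73 (1.07, SE 0.11), with camera adjusted p = 0.0060 and adjusted p = 0.36 with an estimated correlation.

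Genes of striatal neurons, which lie ventral to the dissected region, made the group with the largest median change. Of 20 tested, 17 were lower in KO and 1 higher, also adjusted over the list alone (median -2.62, camera adjusted p = 1.9e-10, adjusted p = 0.063 with an estimated correlation). Rxrg, a retinoid receptor, fell from 51.5 ± 3.7 to 2.51 ± 0.47 CPM, the adenosine receptor Adora2a from 35.5 ± 0.52 to 4.89 ± 0.75 CPM and the signalling protein Ppp1r1b from 104 ± 2.1 to 23.7 ± 1.6 CPM. Of 28 interneuron genes, 18 were lower and 5 higher, also adjusted over the list alone, with Sp9 at -1.81 (SE 0.09) and Dlx6 at -2.49 (SE 0.14), and with camera adjusted p = 6.4e-04 and adjusted p = 0.18 with an estimated correlation. The interneuron call was lost among genes sharing no 31-base word (camera adjusted p = 0.29).

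Glial groups were lower in KO. Of 19 astrocyte genes 17 were lower and none higher, also adjusted over the list alone (median -1.51, camera adjusted p = 4.2e-09, adjusted p = 0.10 with an estimated correlation), including the matrix proteoglycan Bcan (-1.97, SE 0.06), the bicarbonate transporter Slc4a4 (-1.51, SE 0.09) and the glutamate transporter Slc1a2 (-1.51, SE 0.08). Of 19 oligodendrocyte lineage genes 18 were lower and 1 higher, also adjusted over the list alone (camera adjusted p = 1.5e-07, adjusted p = 0.073 with an estimated correlation), with Olig1 at -1.13 (SE 0.07) and Bcas1 at -2.52 (SE 0.20). Of 19 microglia and macrophage genes 12 were lower and none higher (13 lower adjusted over the list alone), among them Cx3cr1 (-1.27, SE 0.09) and the purinergic receptor P2ry12 (-1.53, SE 0.15). Camera gave that list adjusted p = 1.5e-04, and adjusted p = 0.18 with an estimated correlation.

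Of 33 presynaptic genes 25 were lower and 3 higher, also adjusted over the list alone (camera adjusted p = 1.7e-08, adjusted p = 0.24 with an estimated correlation), including Nrxn3 (-1.28, SE 0.06) and the complexin Cplx1 (-0.84, SE 0.05). Of 36 glutamate receptor and postsynaptic genes 22 were lower and 3 higher (23 and 3 adjusted over the list alone), with Grin1 at -1.05 (SE 0.06) and Grm5 at -0.95 (SE 0.06). Of 17 GABA receptor genes 14 were lower (15 adjusted over the list alone), with Gabbr2 at -0.92 (SE 0.05) and Gabra2 at -1.79 (SE 0.12). Of 38 voltage-gated ion channel genes 24 were lower and 4 higher (25 and 4 adjusted over the list alone), with Kcnh1 at -3.20 (SE 0.16) and Hcn2 at -1.03 (SE 0.07). Camera adjusted p for these 3 lists was 3.0e-05, 2.5e-06 and 9.3e-05, and each had adjusted p = 0.18 with an estimated correlation. Of 14 mitochondrially encoded genes 10 were lower and none higher, also adjusted over the list alone, with mt-Nd1 at -0.87 (SE 0.05) and mt-Nd2 at -1.06 (SE 0.07), camera adjusted p = 6.4e-04 and adjusted p = 0.18 with an estimated correlation.

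Among single genes with the largest folds, Crabp1, a retinoic acid binding protein, was 94.4-fold lower in KO (0.332 ± 0.076 against 31.6 ± 1.9 CPM), and Nts, the neurotensin precursor, was lower by a log2 fold change of -4.81 (2.04 ± 1.4 against 57.3 ± 5.5 CPM), or -5.52 without KO replicate 1. Emx2os (2.83, SE 0.20) and Eps8l1 (2.80, SE 0.40) were higher. Ttr, the transthyretin gene of the choroid plexus, was higher in KO (4.95, SE 1.48, adjusted p = 0.031), and its call was lost without WT replicate 1, 2 or 3, Het replicate 2, or KO replicate 1 or 2 (adjusted p from 0.051 to 0.094). The early-response gene Egr1 was lower (-4.06, SE 1.05, adjusted p = 0.018), with 6217 counts in WT replicate 2 against 740 and 729 in the other WT-labelled libraries, and its call was lost without KO replicate 1, 2 or 3 (adjusted p from 0.055 to 0.063). The Egr1 call was also lost with the replicate block (adjusted p = 0.052) and with only the genotypes compared (adjusted p = 0.055). Without WT replicate 2 the Egr1 value was -2.25 (adjusted p = 9.6e-05). Zfp125 (4.53), Hba-a2 (4.42), Rnaset2b (3.88) and Zfp984 (2.81) were higher and Rpsa-ps10 (-10.56), Vcp-rs (-6.79), Rps2-ps10 (-4.66) and Rpl3-ps1 (-4.63) lower in log2 fold change. These 8 share 49.4% to 97.4% of their 31-base words with other genes, so their values are uncertain. The Zfp984 call was lost without any 1 library except WT replicate 2 (adjusted p from 0.065 to 0.0997), and WT replicate 2 had 2.27 CPM of Zfp984 against 0.045 and 0 in the other WT-labelled libraries. Without WT replicate 2 the fitted Zfp984 value was 7.66, which rests on a WT level near 0 and depends on the prior count.

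Het-labelled tissue differed from WT-labelled tissue in many of the same groups. Neurog2 was 4.59-fold higher in Het (log2 fold change 2.20, SE 0.11, adjusted p = 2.0e-10, n = 3 per group) and Slc17a7 was 1.97-fold lower (-0.98, SE 0.06). Hprt, the purine salvage enzyme gene on the X chromosome (52988137 to 53021659), was 36.8-fold lower in Het, at 1.15 ± 0.48 CPM against 42.3 ± 0.74 in WT and 35.9 ± 0.78 in KO. In all 7011 genes were called, 3434 higher and 3577 lower, and 2518 changed at least 1.5-fold. Limma on log2(FPKM + 1) placed 59.0% of its calls on the higher side and upper-quartile scaling factors 55.5%, against 49.0% here. Without WT replicate 3 the share was 48.0%.

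All 20 striatal genes were lower in Het, also adjusted over the list alone (median -2.88, camera adjusted p = 5.6e-16). This was the 1 list call held with an estimated correlation (adjusted p = 0.039 with an estimated correlation). Examples are Rxrg (-4.29, SE 0.12), Adora2a (-2.86, SE 0.11) and the retinoic acid receptor Rarb (-3.84, SE 0.14). Of 19 astrocyte genes 18 were lower, also adjusted over the list alone, with Bcan at -1.43 (SE 0.06) and Slc1a2 at -1.17 (SE 0.08). Of 19 oligodendrocyte lineage genes 17 were lower and 1 higher (18 and 1 adjusted over the list alone), with Olig1 at -1.23 (SE 0.07) and the myelin enzyme Cnp at -1.02 (SE 0.08). Of 19 microglia and macrophage genes 15 were lower, also adjusted over the list alone, with the complement gene C1qa at -1.21 (SE 0.10) and P2ry12 at -1.61 (SE 0.15). Camera adjusted p for these 3 lists was 1.8e-09, 1.6e-08 and 1.9e-06, with adjusted p = 0.090, adjusted p = 0.076 and adjusted p = 0.11 with an estimated correlation.

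Of 32 cell cycle genes 24 were higher in Het and none lower (26 adjusted over the list alone), including Rrm2 (0.69, SE 0.08) and the mitotic kinesin Kif11 (0.82, SE 0.10), with camera adjusted p = 2.4e-08 and adjusted p = 0.090 with an estimated correlation. Of 17 intermediate progenitor genes 12 were higher and 1 lower, also adjusted over the list alone, with Neurod1 at 1.12 (SE 0.09), camera adjusted p = 2.4e-05 and adjusted p = 0.17 with an estimated correlation. Of 15 Cajal-Retzius genes 9 were higher, also adjusted over the list alone, with Trp73 at 1.18 (SE 0.11) and the secreted guidance protein Reln at 0.81 (SE 0.08), camera adjusted p = 0.0020 and adjusted p = 0.30 with an estimated correlation. Of 20 endothelial genes 13 were higher and 1 lower, also adjusted over the list alone, with the glucose transporter Slc2a1 at 0.54 (SE 0.09), camera adjusted p = 0.0067 and adjusted p = 0.11 with an estimated correlation.

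Presynaptic genes were lower in 23 of 33 cases and higher in 1, also adjusted over the list alone, with the syntaxin Stx1a at -0.66 (SE 0.05), camera adjusted p = 2.4e-08 and adjusted p = 0.27 with an estimated correlation. Of 36 glutamate receptor and postsynaptic genes 20 were lower and 2 higher, with Grin1 at -0.81 (SE 0.06) and the scaffold Shank3 at -0.96 (SE 0.09). Of 17 GABA receptor genes 12 were lower, with Gabra2 at -1.68 (SE 0.12). Counts for both lists were equal when adjusted over the list alone, and both had adjusted p = 0.27 with an estimated correlation, beside camera adjusted p of 2.2e-04 and 6.0e-05. Of 38 ion channel genes 19 were lower and 5 higher (19 and 6 adjusted over the list alone), with Hcn2 at -0.92 (SE 0.07), camera adjusted p = 0.0029 and adjusted p = 0.28 with an estimated correlation. Of 28 interneuron genes 15 were lower and 5 higher, also adjusted over the list alone, with Sp9 at -1.80 (SE 0.09), camera adjusted p = 0.022 and adjusted p = 0.36 with an estimated correlation. The interneuron call was lost among genes with under 5% of 31-base words shared (adjusted p = 0.17) and among those sharing none (adjusted p = 0.31). Of 14 mitochondrially encoded genes 9 were lower, with mt-Nd1 at -0.75 (SE 0.05), and of 21 immediate early genes 5 were lower and 1 higher, with Egr4 at -3.03 (SE 0.31), also adjusted over the list alone. Camera gave these 2 lists adjusted p = 0.0013 and adjusted p = 0.032, and adjusted p = 0.17 and adjusted p = 0.72 with an estimated correlation. The call of immediate early genes was lost without WT replicate 2 (adjusted p = 0.22) and without Het replicate 2 (adjusted p = 0.067). Zfp125 (4.66), Hba-a2 (3.98), Rnaset2b (3.62), Zfp984 (2.88) and the linker histone Hist1h1c (3.06) were higher in log2 fold change, and Rpsa-ps10 (-9.48, or -10.71 without Het replicate 3), Vcp-rs (-6.83), Rpl3-ps1 (-4.40) and Rps2-ps10 (-4.40) were lower. All but Hist1h1c share 49.4% to 97.4% of their words with other genes, and the Zfp984 call was lost without any 1 library except WT replicate 2 (adjusted p from 0.068 to 0.097), where the fitted value was 7.73.

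**Figure D2:**
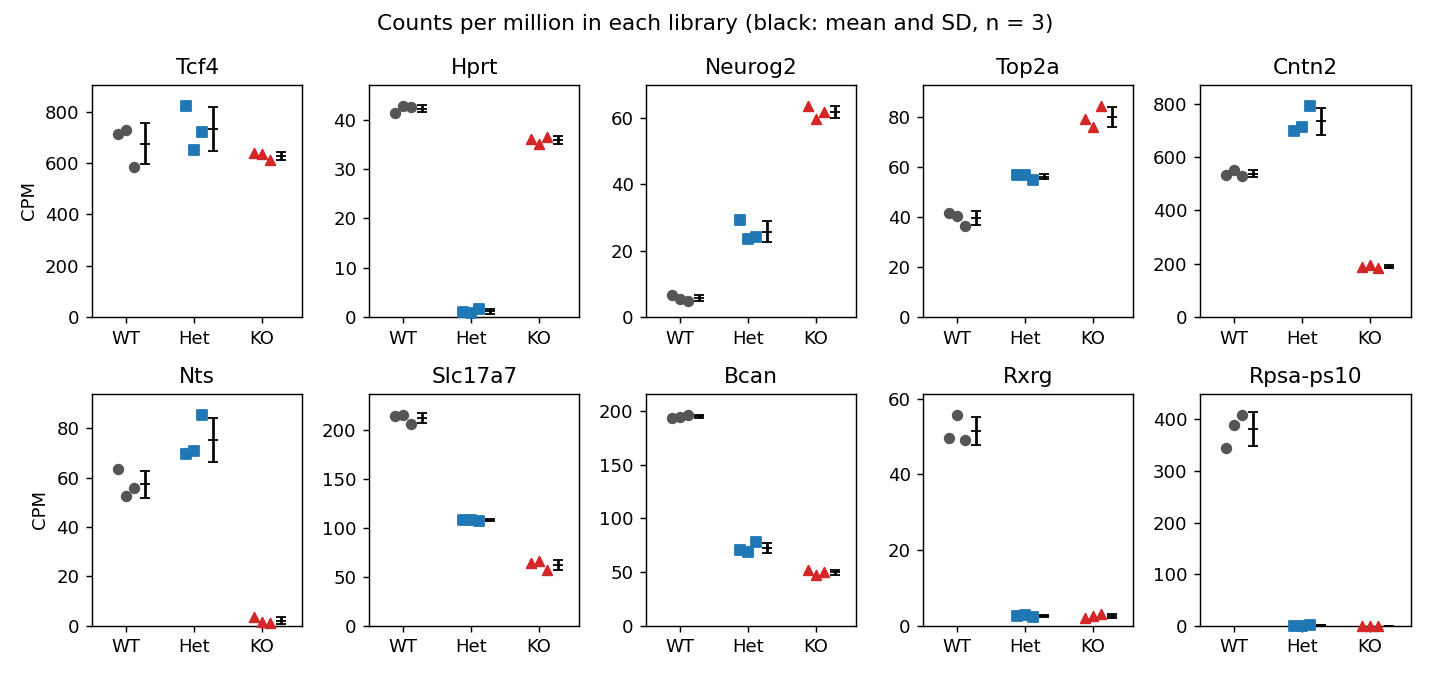
CPM of 10 genes in each library (points, by labelled genotype) with the mean and SD of 3 libraries (black), on linear axes that start at 0. Hprt is near 0 in the Het-labelled libraries alone, Nts in the KO-labelled libraries, and Rxrg and Rpsa-ps10 are high in the WT-labelled libraries alone.

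KO-labelled and Het-labelled tissue differed in fewer genes. Cntn2, an axonal adhesion molecule of the immunoglobulin family, was 3.89-fold lower in KO than Het (log2 fold change -1.96, SE 0.06, adjusted p = 1.1e-12), at 189 ± 6.0 against 735 ± 50 CPM (SD, n = 3). Nts was 36.8-fold lower (2.04 ± 1.4 against 75.4 ± 8.8 CPM, log2 fold change -5.20, or -5.92 without KO replicate 1), the activin antagonist Fst was lower by a log2 fold change of -3.46 and the Wnt ligand Wnt7b was 2.11-fold lower. Neurog2 (1.27, SE 0.09) and Neurod1 (1.05, SE 0.09) were higher in KO. In all 2556 genes were called, 1267 higher and 1289 lower in KO, and 735 changed at least 1.5-fold. Without KO replicate 1 the count was 1467 and without KO replicate 2 it was 1432.

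Of 32 cell cycle genes 18 were higher and 1 lower in KO than Het (21 and 1 adjusted over the list alone), including Top2a (0.51, SE 0.07) and the spindle factor Tpx2 (0.55, SE 0.07), with camera adjusted p = 7.2e-10 and adjusted p = 0.17 with an estimated correlation. Of 16 subplate genes 7 were higher and 2 lower (9 and 2 adjusted over the list alone), with the complexin Cplx3 at 2.18 (SE 0.25) and Abca8a at 1.29 (SE 0.09). Of 27 radial glia genes 8 were higher and 1 lower, also adjusted over the list alone, with Pax6 at 0.51 (SE 0.07) and Sox2 at 0.42 (SE 0.06). Of 22 Notch pathway genes 5 were higher, also adjusted over the list alone, with Mfng at 0.53 (SE 0.09), and of 24 bHLH and Id genes 9 were higher and 3 lower (10 and 3 adjusted over the list alone). Camera adjusted p was 0.0034 for the subplate and Notch lists and 0.020 for the radial glia and bHLH lists, with adjusted p = 0.25, adjusted p = 0.43, adjusted p = 0.54 and adjusted p = 0.47 with an estimated correlation for subplate, Notch, radial glia and bHLH. The radial glia call was lost without Het replicate 2 or KO replicate 1 (adjusted p = 0.11 and 0.080), and the bHLH call without Het replicate 2, KO replicate 1 or KO replicate 3 (adjusted p up to 0.091).

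Of 19 upper-layer neuron genes 8 were lower and 3 higher in KO (10 and 5 adjusted over the list alone), with the secreted Dkk3 at -1.25 (SE 0.07), the semaphorin receptor Plxnd1 at -0.97 (SE 0.08) and Limch1 at -0.77 (SE 0.06). Of 66 axon guidance and adhesion genes 21 were lower and 11 higher (26 and 14 adjusted over the list alone), with Sema7a at -0.86 (SE 0.06) and Pcdh9 at -0.84 (SE 0.06). Of 38 ion channel genes 8 were lower and 3 higher (11 and 3 adjusted over the list alone), with the potassium channels Kcna1 at -1.86 (SE 0.14) and Kcnq5 at 0.71 (SE 0.06). Of 17 GABA receptor genes 7 were lower and 1 higher (10 and 1 adjusted over the list alone), with Gabra5 at -0.51 (SE 0.07). Camera adjusted p was 0.020 for axon guidance and 0.0034 for the other 3 lists, with adjusted p = 0.43 for the upper-layer and ion channel lists and adjusted p = 0.47 for the axon guidance and GABA receptor lists with an estimated correlation. The axon guidance call was also lost after removal of GC and length trends (adjusted p = 0.12).

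Of 28 interneuron genes 7 were lower and 2 higher (9 and 3 adjusted over the list alone), with Nxph1 at -1.42 (SE 0.13). Of 19 astrocyte genes 5 were lower, also adjusted over the list alone, with Bcan at -0.54 (SE 0.06). Of 20 endothelial genes 6 were lower and 2 higher (7 and 2 adjusted over the list alone), with Erg at -0.91 (SE 0.14). Of 33 presynaptic genes 10 were lower and 3 higher (11 and 3 adjusted over the list alone), with the synaptotagmin Syt4 at -1.06 (SE 0.06) and Slc17a7 at -0.79 (SE 0.06). Of 36 glutamate receptor and postsynaptic genes 9 were lower and 3 higher (12 and 3 adjusted over the list alone), with Grik3 at -0.60 (SE 0.06). Camera adjusted p for these 5 lists was 0.020, 0.020, 0.017, 0.034 and 0.043, with adjusted p = 0.47, adjusted p = 0.47, adjusted p = 0.25, adjusted p = 0.57 and adjusted p = 0.54 with an estimated correlation. Removal of GC and length trends ended the presynaptic and glutamate receptor calls (adjusted p = 0.17 and 0.26), and limma's fry ended both and the astrocyte call (adjusted p = 0.069, 0.094 and 0.069). Removal of Y-linked genes, Xist and genes within 20 Mb of Tcf4 ended the glutamate receptor call (adjusted p = 0.075). The list median was then -0.077, against -0.074 with all genes. The endothelial call was lost among genes with under 5% of 31-base words shared (adjusted p = 0.077). Calls were also lost for interneurons without Het replicate 1 or KO replicate 2, for astrocytes without Het replicate 3 or KO replicate 2, for presynaptic genes without Het replicate 2 or KO replicate 3, and for glutamate receptor genes without Het replicate 3 or KO replicate 3 (adjusted p from 0.052 to 0.16). Hprt (4.96, SE 0.15), Adgrg6 (2.17, SE 0.19), Txnip (1.87, SE 0.26) and Maff (1.76, SE 0.18) were higher in KO, and Crabp1 (-2.64, SE 0.23), the desmosomal cadherin Dsc3 (-2.44, SE 0.19) and the phosphatase Dusp5 (-2.21, SE 0.22) were lower.

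**Figure D3:**
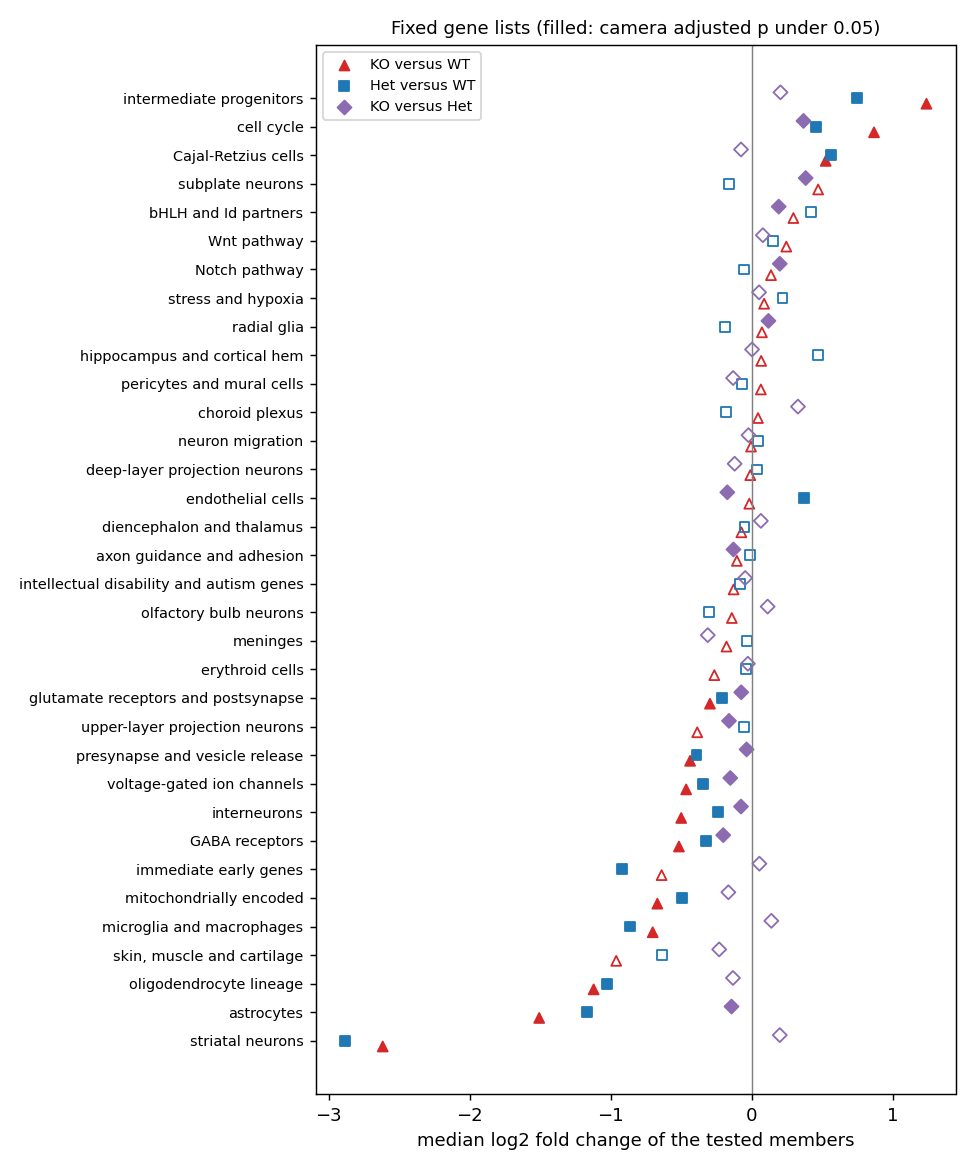
Median log2 fold change of the tested members of 34 gene lists in the 3 comparisons, with filled symbols where the camera adjusted p was under 0.05. The striatal list has medians of -2.62 and -2.88 against WT and 0.20 between KO and Het.

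Across 15271 genes the log2 fold changes of Het versus WT and KO versus WT had r = 0.90. In 20 simulations of unchanged groups the mean r was 0.52. All 9 simulated libraries were drawn gene by gene at the mean rates of the WT-labelled libraries. A shift common to the real WT-labelled libraries is therefore absent from the simulated values. The covariance was 0.680, against 0.0211 simulated, a difference of 0.659. Genes are not independent replicates. Both comparisons called 2713 genes higher and 2874 lower, against 909 and 941 for independent lists of those sizes, and 80 in opposite directions. The 3 WT-labelled libraries could not be split with 2 in each part, so some of the excess may come from the shared libraries. Cntn2 was higher in Het than WT (0.45, SE 0.06) and lower in KO (-1.51, SE 0.06). A test of any genotype difference called 8846 genes.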

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

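Shared-word restrictions and GC and length trends were chosen after seeing the data. Among named genes other than Tcf4, 2602 values in other settings kept their side of the threshold, 55 lost a call and 8 gained one. None changed direction with a call in either setting. A change of direction without a call in either setting was counted among the 2602. Among list results 1954 kept their side of the threshold, 84 lost a call, 49 gained one and 1 changed direction with a call. The 1954 include uncalled lists whose direction changed, such as meninges in KO versus WT (up by camera, down by fry). With genes sharing no 31-base word (3585 of 15271 genes), called genes numbered 1939 (KO versus WT), 1722 (Het versus WT), 758 (KO versus Het) and 2180 (any difference), and called lists 5, 6 and 2, with fewer genes tested. Calls lost there were intermediate progenitors and interneurons in KO versus WT (adjusted p = 0.13 and 0.29), interneurons, endothelial and immediate early genes in Het versus WT (0.31, 0.072 and 0.11), and in KO versus Het interneurons and ion channels (0.35 and 0.31) and astrocytes, bHLH, Notch and axon guidance (each 0.59). With under 5 members left, cell cycle, Cajal-Retzius, oligodendrocyte, mitochondrial, glutamate receptor, GABA receptor, radial glia and upper-layer lists could not be tested there. In KO versus Het the presynaptic list then had a median of 0.0094 (adjusted p = 0.88) and the axon guidance list one of 0.018, and without KO replicate 3 the presynaptic median was 0.0057, against -0.036 and -0.13 with all genes and libraries. The looser restriction to under 5% of words shared (10256 genes), added after that result was seen, gave 5694, 5019 and 2114 genes, 6350 for any difference, and 12, 14 and 8 lists. It ended the interneuron call in Het versus WT (adjusted p = 0.17) and, in KO versus Het, those of radial glia, presynapse, glutamate receptors, interneurons, endothelial cells and bHLH genes (adjusted p from 0.051 to 0.10). A fold of at least 1.5 left 3420, 2518 and 735 genes. An estimated correlation left 0, 1 and 0 lists, and fry called 27, 20 and 12, against 13, 15 and 14 by camera with the preset correlation. Fry ended 5 of the camera calls: radial glia, astrocytes, glutamate receptors and presynapse in KO versus Het, and immediate early genes in Het versus WT. Removal of GC and length trends ended the axon guidance, glutamate receptor and presynaptic calls in KO versus Het (adjusted p = 0.12, 0.26 and 0.17). The stricter filter of 1 CPM in 3 libraries ended the immediate early call in Het versus WT (adjusted p = 0.055). Leaving out 1 library gave 1432 to 2561 genes in KO versus Het, Tcf4 log2 fold changes of -0.20 to -0.046 for KO versus WT, 0.021 (without WT replicate 3) to 0.21 (without Het replicate 2) for Het versus WT and -0.31 to -0.14 for KO versus Het. Tcf4 in KO versus Het also passed the threshold with no filter (-0.22, adjusted p = 0.038) and with the genotypes compared alone (-0.23, adjusted p = 0.043), over a range of adjusted p from 0.038 to 0.325. With no filter the correlation of Het and KO fold changes was 0.72. Except for the fewer genes or libraries tested, the cause was not tested.

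Replicate numbers did not pair the libraries: correlations of same-numbered deviations ran from -0.106 to 0.084. With the replicate block 7775, 6641 and 2166 genes were called. The block ended the calls of Tcf7l2 (adjusted p = 0.064), Ttr (0.080), Egr1 (0.052) and Zfp984 (0.075) in KO versus WT. In Het versus WT it ended those of Tcf7l2 (0.060) and Zfp984 (0.079). Low counts limit genes such as Crabp1 in KO, with 28 counts over the 3 libraries.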

Other observations

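All tests of explanations below were chosen after the results were seen, except the median of the neighbours of Hprt and the regroupings of libraries, whose division by the WT-labelled libraries was made after their counts were seen.

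Several fixed lists did not pass the test in KO versus WT although members did. Of 24 bHLH and Id genes 12 were higher and 6 lower (camera adjusted p = 0.087), and of 42 Wnt pathway genes 20 were higher and 9 lower (camera adjusted p = 0.092). Of 19 upper-layer neuron genes 11 were lower and 6 higher (camera adjusted p = 0.087), and of 39 intellectual disability and autism genes 18 were lower and 9 higher (camera adjusted p = 0.13).

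For the distance of the WT-labelled libraries from the other 6, different assignment of reads between near-identical copies is argued against as the whole cause, since 48.0% of genes sharing no 31-base word were called in Het versus WT, against 21.1% in KO versus Het. A GC and length trend is argued against in the same way, with 46.7% called after its removal, against 18.5%. Assignment between copies may account for some processed pseudogenes. Of 207 tested, 51 were lower and 16 higher in Het than WT, and 5 were lower in KO than Het. Of the 135 that share at least 50% of their words with a protein-coding parent, 41 were lower and 8 higher in Het than WT. None of the 135 was called between KO and Het. Of the 36 parents of the lower ones, 86.1% had a positive fold in Het (exact 95% interval 70.5% to 95.3%). That interval takes parents as independent, which genes of the same libraries are not. The median log2 fold change was 0.32 for these parents and 0.062 over all 672 tested parents, of which 178 were higher and 103 lower. Rpl34-ps1 went from 49.4 to 0.025 CPM and its parent Rpl34 from 165 to 357 CPM, so reads of this copy could make up only part of the parent's rise. Rpsa-ps10 went from 381 to 0.51 CPM and Rpsa from 1018 to 1251 CPM, so reads of that copy could make up the whole rise of Rpsa. A later stage of the WT-labelled tissue and the genotype cannot be told apart in this design: 7 of 7 lists had the direction a later stage gives, but their directions had been seen when they were chosen, so this count supports neither. A difference in how the WT-labelled libraries were prepared, sequenced or aligned would also coincide with that label. It could not be told apart from genotype in either comparison with WT, and was not tested.

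Striatal genes were mostly highest in the WT-labelled libraries: of 20 tested, all were lower in Het than WT, and 17 were lower and 1 higher in KO than WT. Shared reads are argued against for the 16 members with under 5% of words shared, 100% of which were called lower in Het. As all 20 were lower, that share could not have differed, and the argument rests on how few words these 16 share. A graded effect of Tcf4 dose on the list as a whole is argued against, since the list mean was 0.22 log2 CPM higher in KO than Het (pooled SD 0.13). Members went both ways: in KO versus Het 3 of the 20 were higher and 2 lower, with camera adjusted p = 0.15. Ppp1r1b was graded, at 104, 39.2 and 23.7 CPM in WT, Het and KO. Ventral tissue in the WT-labelled dissections and an effect of losing either 1 or both Tcf4 alleles cannot be told apart: 85.0% of the 20 members were lower in both Het and KO, which restates the pattern and supports neither. Isl1, Six3 and Drd2, chosen after their values were seen, went from 12.3, 17.7 and 12.3 CPM in WT to 0.034, 0.63 and 1.14 CPM in Het.

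Hprt was near 0 in the Het-labelled libraries. Reads shared with a copy are argued against, as 0% of its words occur in other transcripts. A graded effect of Tcf4 dose is argued against by a log2 fold change of 4.96 for KO versus Het. An altered Hprt allele in the line of the Het-labelled pups is a candidate explanation that was not tested directly. Hprt was at 35.9 CPM in KO, so line and genotype could then not be told apart in comparisons with Het. The 18 tested genes within 2 Mb, whose median can speak only against a loss over the whole region, had a median log2 fold change of -0.14 for Het versus WT. Of these, 3 were called lower (Gm14584 at -2.12, Rtl8c at -0.52 and Gm14597 at -0.50) and Gpc4 higher (0.51), or 22.2%, against 45.9% of all tested genes, and the processed pseudogene Rps2-ps13, which shares 94.5% of its words with other genes, had -10.58 at adjusted p = 0.058.

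For each pair of genotypes the 6 libraries have 10 splits, too few for a share under 0.05. The real split, 1 of the 10, called 8061 genes in KO versus WT, 7011 in Het versus WT and 2556 in KO versus Het, and the highest other split called 0, 26 and 7. For any genotype difference, 1 of 100 drawn splits of the 9 libraries, the real one, reached 8846 genes. This argues against a random division of the libraries, if each library is an independent sample. It does not bear on other differences that coincide with a label. The 4 other drawn splits that kept the 3 WT-labelled libraries together called 5225 to 5900 genes and the remaining 95 at most 600, so the high counts of other splits go with the distance of the WT-labelled libraries.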
